A study of Homo sapiens with 210 samples.

How the data were processed

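The study measured messenger RNA in left ventricular myocardium from human hearts with Affymetrix oligonucleotide arrays, 1 array per sample. Per the labels' protocols, the tissue was frozen in liquid nitrogen, total RNA was extracted with Trizol and biotin-labelled complementary RNA was hybridised. The 210 arrays fell into 3 groups by their titles. Ischemic cardiomyopathy had 108 arrays and idiopathic dilated cardiomyopathy 86, both from hearts explanted at transplantation, and the nonfailing group had 16 arrays from donor hearts that were not transplanted. The titles number the samples within each group but do not say whether any heart gave more than 1 sample, so p-values measure the spread between these samples. The labels used here hold no covariate such as treatment or processing batch.

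The deposited table holds log2 expression values from robust multi-array average (RMA), a method that corrects background, normalizes across arrays and summarises the probes of a probe set. Per the submitters' processing notes and the series design text, the authors ran RMA on all arrays together, and its version is not given in the sources used here. The values ran from 2.99 to 13.4, and array medians were 6.01. The sorted values of all arrays were nearly identical, with an SD over arrays of at most 0.00109 at any rank. RMA normalizes before it summarises, so a further alignment after it seems likely, though its source was not established here. The arrays had thus been aligned to a common distribution. A difference in total messenger RNA between groups is therefore invisible here, and each change is relative to the other genes on the array. RMA also compresses differences of dim probe sets. Arrays have no read depth, and the number of arrays, above all the 16 nonfailing ones, limits the precision.

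Of 22283 probe sets, 68 were controls, 19065 had 1 gene symbol, 1043 had several and 2107 had none in the annotation used here. Gene IDs matched the RefSeq gene table for 19053 of the 19065, and 0 symbols needed an update. Probe sets with several symbols or none were left out, as were 31 probe sets of XIST and Y-linked genes. For the 4304 genes with more than 1 probe set, the probe set with the highest mean over all arrays stood for the gene. This left 11939 genes. Among the chosen probe sets, 948 carried the suffix x_at, which marks probes that can bind several transcripts, and 4039 the suffix s_at, which marks probes shared by transcripts of a gene or family. Where another probe set of a gene named by the naming rule below pointed the other way, the text says so. Other probe sets of genes named outside that rule were not examined. Sizes also differed between probe sets of a gene, and each size given is that of the chosen probe set. No genome coordinates are given, since the files name no genome build.

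All 210 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8, for reading. Moderated 2-sided tests were run for 3 contrasts, ischemic minus nonfailing, idiopathic minus nonfailing and ischemic minus idiopathic. P-values were adjusted by the Benjamini-Hochberg method over the 11939 genes of a contrast, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene in the text comes from this limma fit unless another test is named. Log2 differences are given with their standard error (SE).

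The genes to be named were fixed by a rule. For each contrast it took the 8 largest rises and the 8 largest falls among called genes whose mean in at least 1 group exceeded the median of all gene means, 6.42. It added a panel, named whether or not it passed, of NPPA, NPPB, MYH6, MYH7, ATP2A2, ACTA1, COL1A1, PPARGC1A and FOXO1. Further forkhead genes meant for this panel were not among the genes measured, whereas the measured members of the forkhead list were analysed in each contrast. The rule also took up to 4 called members, by size of change, from each gene list described.

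Members of 28 gene lists were written down as pathways and cell type markers that a piece of left ventricle can hold. Lists of cardiomyocyte biology covered fetal and stress genes, sarcomere, calcium handling, ion channels and gap junctions, beta-adrenergic signalling, cardiac transcription factors and forkhead transcription factors. Others covered extracellular matrix, TGF-beta and Wnt components, fatty acid oxidation, oxidative phosphorylation, glycolysis, immediate early genes, acute phase and cytokine response, heat shock response, and the natriuretic, angiotensin and endothelin axis. Cell type lists held markers of fibroblasts, endothelium, smooth muscle and pericytes, macrophages and monocytes, neutrophils, lymphocytes, mast cells, erythrocytes, adipocytes, Schwann cells and neurons, mesothelium and epicardium, and atrial cardiomyocytes. Some genes stand in several lists. Lists were tested with camera, a competitive test in limma, at a preset correlation between genes of 0.01, and again with an estimated correlation. The rotation test fry, which asks whether a list's genes move on balance one way, stood beside them. Adjustment was over the 28 lists of a contrast. A permutation test of the mean of each list per array, with 100000 resamples of the array labels, was added after the data had been seen.

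The comparisons of the 2 failing groups with nonfailing tissue share their 16 control arrays. Their overlap was therefore set beside simulated groups without an effect, and beside fits in which each comparison used 8 of the nonfailing arrays.

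Groupings, contrasts, gene lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives covered a filter on dim genes, other choices of the probe set, another normalization and centring, weights and variances per group or array, fits of only the groups compared, a trended robust prior, and covariates for RNA quality and hidden structure. They further covered the replicate number as a block, draws of equal group sizes and a test with unequal variances. Alternatives added after seeing the data left out 10 arrays with poly-A spikes, adjusted for that batch, left out 34 arrays with degraded RNA, centred on 100 normalization probe sets, or adjusted for leukocyte and erythrocyte markers.

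RNA quality was read from control probe sets at the 3' and 5' ends of the GAPDH and beta-actin messages, where degraded RNA gives a larger 3' excess. A GAPDH 3' to 5' signal ratio above 3 marked an array as degraded. A batch was read from 4 bacterial poly-A spike controls, called present at a mean above 6 on the log2 scale.

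The fit was tested on simulated data made from residuals of the real arrays, with 200 of 11939 genes changed, over 20 runs. For ischemic against nonfailing, it recovered 71.3% of genes changed 1.2-fold, 97.9% changed 1.5-fold and 99.9% changed 2-fold, with a median of 25.5 false calls. For idiopathic against nonfailing the shares were 70.2%, 97.4% and 99.8%, with 8.5 false calls. For ischemic against idiopathic they were 95.9%, 99.9% and 100%, with 3.5 false calls. The highest counts of false calls in a run were 382, 295 and 35. With no effect simulated, camera at the preset correlation called a median of 7, 5.5 and 6 of the lists in the 3 contrasts, and with an estimated correlation 1, 0 and 0. The text therefore leads with counts of called members and gives the preset camera p only beside the other tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.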

Results

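Expression of 11939 genes was compared in left ventricular myocardium of 210 hearts, counting each array as 1 heart. Of these 16 were nonfailing donor hearts, 86 had idiopathic dilated cardiomyopathy and the rest, the largest group, had ischemic cardiomyopathy. Ischemic cardiomyopathy is heart failure after loss of coronary blood supply, and idiopathic dilated cardiomyopathy is failure of an enlarged ventricle without a known cause. The series title sets these 3 groups side by side. No 2 arrays held identical values. The correlation between 2 arrays across probe sets ranged from 0.814 to 0.992 with a median of 0.974, and the closest pair still differed with an SD of 0.20 log2 units over genes, against 0.37 for the median pair.

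RNA quality varied within and between groups. The GAPDH 3' minus 5' difference averaged 0.71 ± 0.22 log2 units (SD, n = 16) in nonfailing, 1.11 ± 0.88 (n = 86) in idiopathic and 1.12 ± 0.79 in ischemic arrays. Permutation tests, each 2-sided, gave adjusted p = 0.0700 for ischemic against nonfailing, 0.0861 for idiopathic against nonfailing and 0.941 between the failing groups. The beta-actin measure was higher than in nonfailing arrays by 0.42 in ischemic and 0.47 in idiopathic arrays. For it the same tests gave unadjusted p = 0.0125 and 0.0240, adjusted p = 0.0700 each, and adjusted p = 0.813 between the failing groups. Degraded RNA by the GAPDH ratio was seen in 0 nonfailing, 12 idiopathic and 22 ischemic arrays. Poly-A spike signal marked a batch of 10 arrays, 7 idiopathic, 3 ischemic and 0 nonfailing, and 3764 genes differed between that batch and the other arrays with group in the limma model.

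The first comparison asked which genes differ between ischemic and nonfailing myocardium. ASPN, which encodes the matrix proteoglycan asporin, rose 5.43-fold in ischemic hearts (log2 difference 2.44 ± 0.21 SE, adjusted p = 2.84e-20) and exceeded the nonfailing mean in 98.1% of ischemic arrays. LUM, the collagen-binding proteoglycan lumican, rose 4.18-fold (2.06 ± 0.18), and NPPA, the precursor of atrial natriuretic peptide, rose 3.35-fold (1.74 ± 0.29, adjusted p = 6.64e-07). MYOT, which encodes the Z-disc protein myotilin, fell by 2.27 on the log2 scale (SE 0.19, adjusted p = 7.77e-21) and lay below the nonfailing mean in 97.2% of ischemic arrays. MYH6, the fast alpha myosin heavy chain, fell by 1.42 (SE 0.29, adjusted p = 7.69e-05), while MYH7, the slow beta form, differed by 0.15 ± 0.10 (adjusted p = 0.385). MYH7 was read from its only probe set, of type x_at, so other transcripts may add to its signal. It exceeded the nonfailing mean in 84.3% of ischemic arrays.

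In all, limma called 1581 of 11939 genes, or 13.2%, between ischemic and nonfailing hearts, 824 higher and 757 lower. A change of at least 1.5-fold was reached by 155 of them, 79 higher and 76 lower, and 31 reached 2-fold. The other largest rises were MXRA5, a matrix remodelling gene (1.64), HBB, beta globin (1.54), the collagen chains COL1A1 (1.48) and COL1A2 (1.15), and MATN2, the matrix protein matrilin 2 (1.12). The other largest falls were HOPX (-1.50), a homeodomain cofactor of heart development, FKBP5 (-1.49), a cochaperone of the glucocorticoid receptor, and NRAP (-1.49), an actin anchoring protein of the muscle fibre ends. ANKRD2 (-1.34), a stretch-responsive ankyrin repeat protein, CD163 (-1.34), the haemoglobin scavenger receptor of macrophages, and FCN3 (-1.34), a lectin of the complement system, completed the set. HBB and CD163 were read from x_at probe sets, and 2 of 2 other probe sets of each pointed the same way. The size of the COL1A1 rise rests on 1 of its 4 probe sets, the others differing by 0.63, 0.09 and 0.29. With leukocyte and erythrocyte marker means as covariates, which include HBB itself and so lower its difference by construction, HBB differed by 0.53. With the replicate number as a block, NRAP differed by -0.47 (adjusted p = 0.531).

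**Figure D1:**
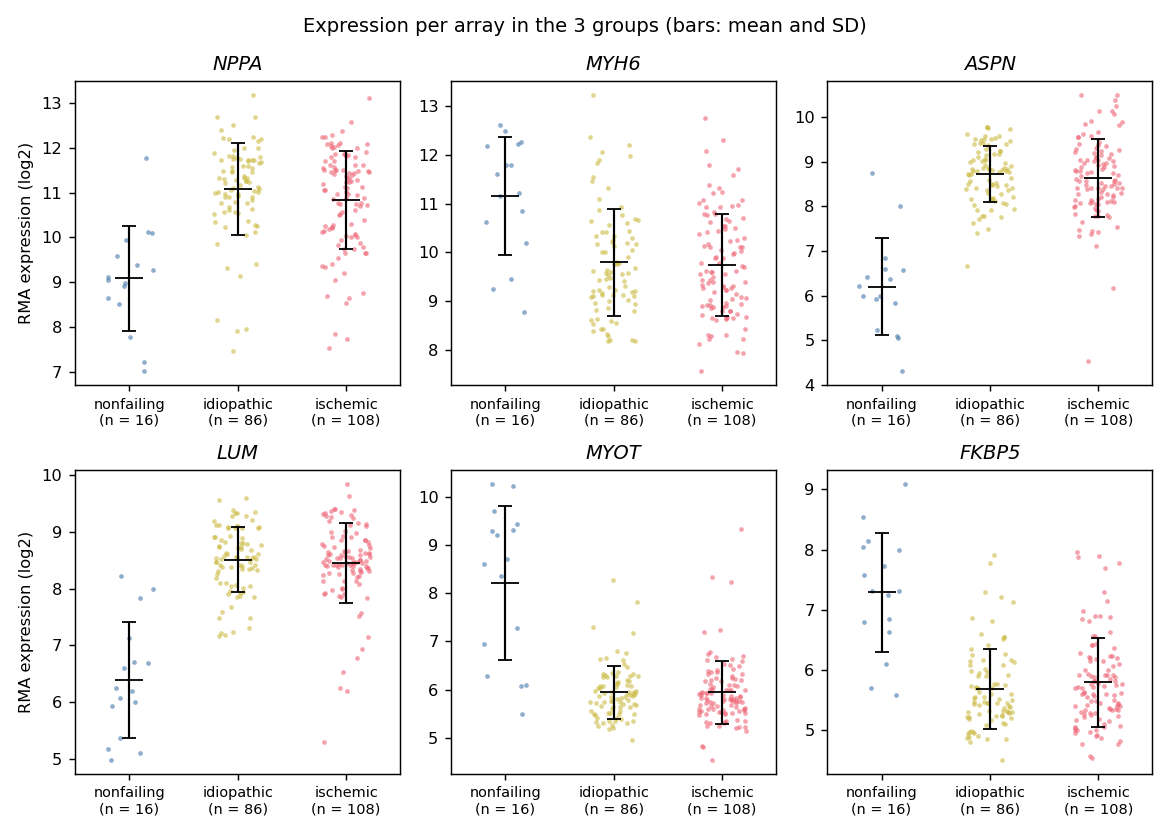
RMA expression (log2) of 6 genes per array in 16 nonfailing, 86 idiopathic and the ischemic hearts, where each point is an array and black bars give the mean and SD. NPPA, ASPN and LUM lie higher and MYH6, MYOT and FKBP5 lower in both failing groups, and nonfailing arrays spread widely, as for MYOT with a mean of 8.21 and an SD of 1.60.

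Matrix and fibroblast genes rose together in ischemic hearts. Of 42 extracellular matrix genes, 27 rose and 2 fell over all genes tested, and 30 rose and 4 fell when adjusted over the list alone. The median difference was 0.48 log2 units (camera adjusted p = 6.69e-16, adjusted p = 0.103 with an estimated correlation, permutation adjusted p = 0.000616). Fibroblast markers rose in 7 of 14 genes and fell in 0, or 9 and 0 adjusted over the list alone, including COL3A1 (1.04), for which 2 of 3 other probe sets had the same sign. Their camera adjusted p = 7.48e-09 compared with adjusted p = 0.0694 with an estimated correlation, and the permutation adjusted p was 0.000187. Among 24 TGF-beta and Wnt components, 5 rose and 1 fell (10 and 2 adjusted over the list alone). The risers were led by the secreted Wnt antagonists SFRP1 (0.91), FRZB (0.89) and SFRP4 (0.81) and the Wnt receptor FZD7 (0.76). Adjusted p = 0.0062 by camera, adjusted p = 0.138 with an estimated correlation and adjusted p = 0.00014 by permutation were found for this list.

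Stress and acute phase genes were lower in ischemic than in nonfailing hearts. In the heat shock response list, 11 of 16 genes fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.38 log2 units. The cochaperone BAG3 (-0.66) and the chaperones HSPA6 (-0.65) and HSPH1 (-0.56) fell, whereas HSPA2, a chaperone with little heat induction, rose (0.60). This was the only list called in this comparison with an estimated correlation (adjusted p = 0.00974, camera adjusted p = 1.47e-10, permutation adjusted p = 0.000616). Of 27 acute phase and cytokine response genes, 11 fell and 1 rose, or 12 and 1 adjusted over the list alone. PTX3, a long pentraxin (-1.34), SERPINA3, a protease inhibitor of the acute phase (-1.31), the metallothionein MT1X (-0.77) and the monocyte chemokine CCL2 (-0.73) fell most. PTX3 was dim, with means of 5.20 in nonfailing, 3.85 in ischemic and 3.73 in idiopathic hearts, so the size of its fall is uncertain. Camera gave adjusted p = 2.48e-09 for it, with adjusted p = 0.0694 with an estimated correlation and permutation adjusted p = 0.00108. Of 23 immediate early genes, which respond within minutes to stimuli, 6 fell and 1 rose (7 and 1 adjusted over the list alone). FOSL1 (-0.73), MYC (-0.69) and ATF3 (-0.66) fell and EGR1 (0.65) rose. Their camera adjusted p = 0.00254 contrasted with adjusted p = 0.524 with an estimated correlation and a permutation adjusted p of 0.226.

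Most members of the cardiomyocyte lists were not called. Over all genes tested 13.2% were called in this comparison, and some of these lists held a larger share. The 9 measured fetal and stress genes split into 2 that rose, NPPA and the ubiquitin hydrolase UCHL1 (0.32), 1 that fell and 6 that were not called, and 2 rose and 2 fell adjusted over the list alone. NPPB, the precursor of B-type natriuretic peptide, differed by -0.21 ± 0.47 (adjusted p = 0.832) and had an SD of 2.37 log2 units among nonfailing hearts. Skeletal actin ACTA1 differed by -0.38 ± 0.14 (adjusted p = 0.0562), and the calcium pump ATP2A2 by -0.14 ± 0.11 (adjusted p = 0.459). The dimmer probe sets of ATP2A2 differed by more, -0.58 and -0.42, so its level was not settled here. In the sarcomere list, 3 of 17 rose, the M-band genes MYOM2 (0.52) and MYOM1 (0.48) and the thin filament gene NEBL (0.46, sign shared by 3 of 4 other probe sets), and MYH6 fell. Adjusted over the list alone the counts were 4 and 1. For calcium handling, 0 of 17 were called, in either adjustment. Ion channels and gap junctions had 3 risers and 3 fallers among 18 (4 and 5 adjusted over the list alone), among them the gap junction gene GJA1 (0.66), the potassium channels KCNJ4 (0.49) and KCNA5 (0.31) and the sodium pump subunit ATP1B1 (-0.34). The other probe set of KCNJ4 pointed the other way. Beta-adrenergic signalling had 1 riser, GNAS (0.22), and 1 faller, PDE4D (-0.42), among 20, both over all genes and adjusted over the list alone. Only 5 of 8 other probe sets of GNAS and 2 of 3 of PDE4D shared the sign.

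Most members of the transcription factor lists were not called either. Of 27 measured forkhead genes, out of 38 written, 1 fell in either adjustment, FOXK2 (-0.22 ± 0.05, adjusted p = 6.27e-05), and FOXO1 differed by -0.01 ± 0.07, with its other probe set at 0.04. This list was written with knowledge of the study's interest in the family, so its count is not independent evidence. Cardiac transcription factors had 2 risers, MEF2A (0.27) and NFATC1 (0.16), and 2 fallers, TEAD4 (-0.31) and ESRRA (-0.19), among 23, or 3 and 6 adjusted over the list alone. PPARGC1A, a coactivator of mitochondrial genes, differed by 0.12 ± 0.11 (adjusted p = 0.543), and 2 of 4 other probe sets of NFATC1 shared its sign.

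No metabolic list was called with an estimated correlation or by permutation, and most of their members were not called. Oxidative phosphorylation had 3 risers among 40, NDUFS1 (0.34), NDUFA8 (0.25) and ATP5PB (0.23), and 0 adjusted over the list alone (camera adjusted p = 0.0235, adjusted p = 0.881 with an estimated correlation, permutation adjusted p = 0.397). Fatty acid oxidation had 2 risers among 25 in either adjustment, ETFB (0.31) and ECHS1 (0.23). In the glycolysis list, 2 of 22 rose and 3 fell, or 4 and 5 adjusted over the list alone. PDK4, a kinase that restrains pyruvate oxidation (-1.18), the hexokinase HK2 (-0.40) and the lactate dehydrogenase LDHA (-0.31) fell, and TPI1 rose (0.20), with 1 of its 2 other probe sets pointing the same way. The natriuretic, angiotensin and endothelin axis had 3 risers, CORIN, the protease that activates natriuretic peptides (0.80), NPR3 (0.53) and MME (0.22), and 1 faller, the endothelin receptor EDNRB (-0.44), among 17 in either adjustment.

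Most markers of other cell types were not called, though some lists held a larger share of calls than the 13.2% of all genes. T, B and NK lymphocyte markers had 4 risers and 0 fallers among 19 (6 and 0 adjusted over the list alone), among them CCL5 (0.32), TRBC1 (0.25), CD8A (0.19) and IL2RB (0.16). Mast cell markers had 4 risers and 0 fallers among 9 in either adjustment, KIT (0.33), HPGDS (0.24), CPA3 (0.24) and HDC (0.13). Camera gave adjusted p = 0.00609 and 0.0138 for these lists, adjusted p = 0.434 and 0.201 with an estimated correlation, and permutation adjusted p = 0.00159 and 0.00108. Erythrocyte markers had 3 risers among 7 in either adjustment, HBB, HBD (0.28) and ALAS2 (0.16), of which HBD and ALAS2 changed sign with leukocyte and erythrocyte covariates. Their camera adjusted p = 0.0235 compared with adjusted p = 0.398 with an estimated correlation and permutation adjusted p = 0.00014. Atrial markers had 3 risers among 11, NPPA, KCNA5 and BMP10 (0.16), or 5 adjusted over the list alone (camera adjusted p = 0.0427, adjusted p = 0.398 with an estimated correlation, permutation adjusted p = 0.00103). Adipocyte markers had 2 fallers among 13 in either adjustment, ADH1B (-0.74) and RBP4 (-0.69), with camera adjusted p = 0.0186, adjusted p = 0.68 with an estimated correlation and permutation adjusted p = 0.127.

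Macrophage and monocyte markers split. The resident macrophage genes CD163, LYVE1 (-0.72) and VSIG4 (-0.60) fell, and the growth factor receptor CSF1R (0.37) was 1 of 2 that rose among 18, against 3 risers and 3 fallers adjusted over the list alone. Neutrophil markers had 1 faller among 13, the calgranulin S100A9 (-0.76), or 2 adjusted over the list alone. Endothelial markers had 1 faller, FCN3, and 1 riser, RAMP2 (0.28), among 15 in either adjustment. Smooth muscle and pericyte markers had 1 faller, the contractile regulator CNN1 (-1.32), and 3 risers among 14 in either adjustment, RGS5 (0.48), NOTCH3 (0.43) and MYH11 (0.43). The other probe set of NOTCH3 and 1 of 3 of MYH11 pointed the other way. Schwann and neuronal markers had 2 fallers among 12, CDH19 (-0.49) and NCAM1 (-0.41), with 1 riser and 2 fallers adjusted over the list alone. Mesothelial and epicardial markers had 1 riser among 9 in either adjustment, the retinoic acid enzyme ALDH1A2 (0.62, its other probe set 0.00).

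For ischemic against nonfailing hearts, camera at the preset correlation called 12 of the 28 lists, 8 higher and 4 lower, against 1 with an estimated correlation, 9 by fry and 9 by permutation. In the calcium handling, ion channel, glycolysis, beta-adrenergic, natriuretic axis, forkhead, cardiac transcription factor, endothelial, neutrophil and Schwann cell lists, the median, mean and camera direction differed in sign. Without the degraded arrays, which left 86 ischemic hearts, 1631 genes were called, and without the spike batch 1534. A test with unequal variances per gene called 985, and 36 of the 86 named genes called here lost their call in it. Centring on the normalization probe sets called 1792 genes higher and 493 lower against 824 and 757.

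**Figure D2:**
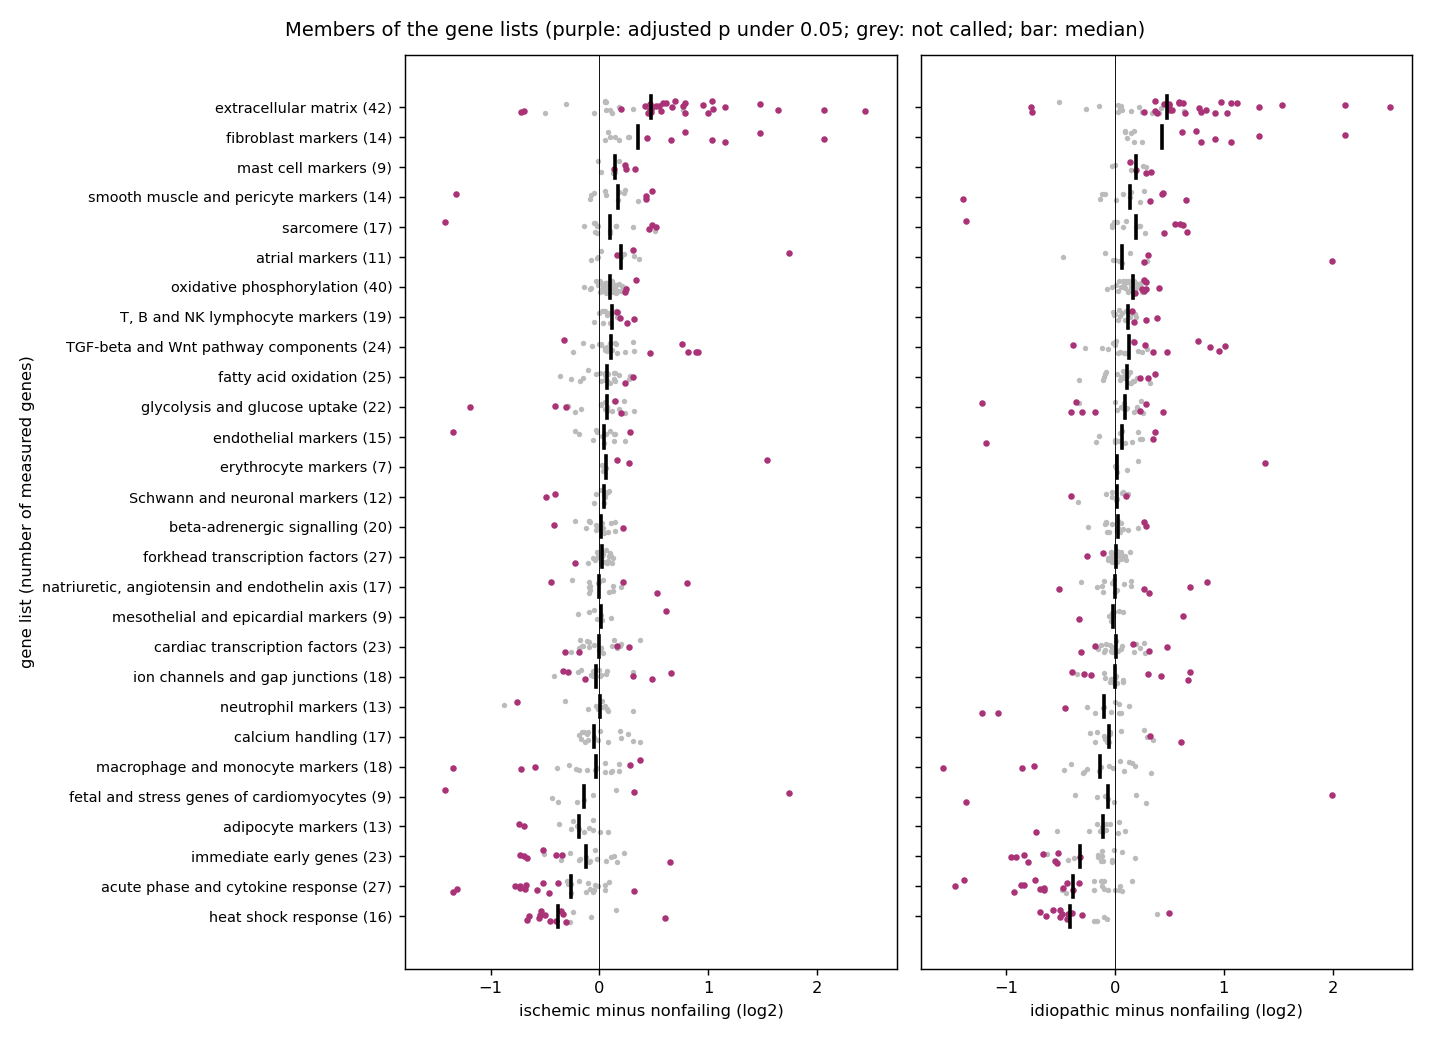
Log2 differences from nonfailing hearts of every measured member of the 28 gene lists, ischemic on the left and idiopathic on the right. Each point is a gene, purple where the adjusted p was under 0.05, and black bars are list medians, which run from -0.38 for the heat shock response to 0.48 for extracellular matrix in ischemic hearts.

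The second comparison asked the same of idiopathic dilated cardiomyopathy. ASPN rose by 2.53 ± 0.22 log2 units (adjusted p = 5.99e-21) and LUM by 2.12 ± 0.18, and both exceeded the nonfailing mean in 86 of 86 arrays. NPPA rose 3.99-fold (SE 0.29 on the log2 scale, adjusted p = 1.33e-08). MYOT fell by 2.26 (SE 0.20) and lay below the nonfailing mean in 85 of 86 arrays, and MYH6 fell by 1.36 (SE 0.29, adjusted p = 0.000171). FKBP5 fell by 1.61 (SE 0.20, adjusted p = 1.69e-11), and CD163 fell by 1.58 (SE 0.27).

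Here limma called 1710 genes, or 14.3% of those tested, 921 higher and 789 lower. Of these, 185 changed at least 1.5-fold (98 higher, 87 lower) and 34 at least 2-fold. MXRA5 (1.54), HBB (1.38), COL1A1 (1.32), MATN2 (1.22) and the basement membrane collagen COL15A1 (1.13) were the other largest rises. ANKRD2 (-1.60), HOPX (-1.50), the secreted phospholipase PLA2G2A (-1.43), the cytochrome P450 CYP4B1 (-1.41) and CNN1 (-1.40) were the other largest falls. The other probe sets of COL1A1 differed by 0.24, 0.03 and 0.04. HBB differed by 0.61 with the leukocyte and erythrocyte covariates, of which it is again a part. From the panel, NPPB differed by -0.06 ± 0.47, MYH7 by 0.19 ± 0.11, ATP2A2 by -0.09 ± 0.11 (other probe sets -0.60 and -0.44), ACTA1 by -0.37 ± 0.14 (adjusted p = 0.074), PPARGC1A by 0.26 ± 0.11 (adjusted p = 0.106) and FOXO1 by -0.05 ± 0.07 (its other probe set at 0.04), none of them called.

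Extracellular matrix genes rose in 25 of 42 and fell in 2, or 28 and 4 adjusted over the list alone, and fibroblast markers rose in 7 of 14 and fell in 0 in either adjustment. The adjusted p was 0.126 with an estimated correlation for the first and 0.0724 for the second, and permutation gave adjusted p = 9.33e-05 for each, from the smallest p that it allowed, 1e-05. TGF-beta and Wnt components rose in 8 of 24 and fell in 1 (10 and 2 adjusted over the list alone), with FRZB (1.01), SFRP1 (0.96), FZD7 (0.87) and SFRP4 (0.76) in front and adjusted p = 0.092 with an estimated correlation.

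Acute phase and cytokine genes fell in 13 of 27 and rose in 0, or 17 and 0 adjusted over the list alone, led by the dim PTX3 (-1.47), SERPINA3 (-1.39), CCL2 (-0.93) and MT1X (-0.87). Heat shock genes fell in 10 of 16 and rose in 1 in either adjustment, with HSPA6 (-0.69), BAG3 (-0.63), HSPH1 (-0.57) and DNAJB1 (-0.51). Both lists kept their call with an estimated correlation (adjusted p = 0.0349 each), and permutation gave adjusted p = 0.00014 and 0.00096. Immediate early genes fell in 9 of 23 and rose in 0 (10 and 0 adjusted over the list alone), with ATF3 (-0.96), the matricellular gene CCN1 (-0.91), FOSL1 (-0.83) and MYC (-0.80). For them camera gave adjusted p = 5.42e-08, adjusted p = 0.126 with an estimated correlation, and permutation adjusted p = 0.00221. Macrophage and monocyte markers fell in 3 of 18 in either adjustment, CD163, LYVE1 (-0.86) and VSIG4 (-0.74), with camera adjusted p = 0.0392, adjusted p = 0.76 with an estimated correlation and permutation adjusted p = 0.102. Neutrophil markers fell in 3 of 13 in either adjustment, S100A8 (-1.22), S100A9 (-1.08) and FPR1 (-0.46, its other probe set opposite), with adjusted p = 0.662 with an estimated correlation and permutation adjusted p = 0.00369.

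Oxidative phosphorylation genes rose in 8 of 40 and fell in 0, or 11 and 0 adjusted over the list alone, among them NDUFS1 (0.41), NDUFA8 (0.28), UQCRC2 (0.28) and NDUFB5 (0.27). This list had camera adjusted p = 2.96e-05, adjusted p = 0.673 with an estimated correlation, and permutation adjusted p = 0.00339. Sarcomere genes rose in 5 of 17 and fell in 1 in either adjustment, with MYOM2 (0.66), MYOM1 (0.60) and LDB3 (0.62, sign shared by 2 of 3 other probe sets), adjusted p = 0.76 with an estimated correlation and permutation adjusted p = 0.0354. Calcium handling had 2 risers among 17, the sarcoplasmic reticulum proteins HRC (0.60) and CASQ2 (0.32), or 4 risers and 1 faller adjusted over the list alone. Forkhead genes fell in 2 of 27, FOXK2 (-0.25) and the dim FOXL2 (-0.11), or 1 adjusted over the list alone. Mast cell and lymphocyte markers rose in 4 of 9 and 4 of 19 (7 and 6 adjusted over the list alone), with adjusted p = 0.126 and 0.454 with an estimated correlation.

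For idiopathic against nonfailing hearts, 12 lists were called by camera at the preset correlation, 7 higher and 5 lower, against 2 with an estimated correlation, 9 by fry and 14 by permutation. The sign differed between the median, mean and camera direction in 7 lists of this comparison, those of fetal genes, calcium handling, ion channels, glycolysis, forkhead genes, Schwann cells and mesothelium. Without the degraded arrays 1897 genes were called, from 74 idiopathic hearts, and without the spike batch 1620. The test with unequal variances per gene called 1186, and 30 of the 93 named genes called here lost their call in it. Centring on the normalization probe sets called 1275 genes higher and 570 lower against 921 and 789.

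Changes from nonfailing hearts were shared by both forms of failure. The matrix genes ASPN and LUM, the natriuretic peptide gene NPPA and the falling genes MYOT and FKBP5 were called in both. In all, 1345 genes were called in both in the same direction, 700 higher and 645 lower, and 0 in opposite directions. A further 236 were called only against ischemic and 365 only against idiopathic hearts, which does not show a difference between them. Independent lists of these sizes would share 63.6 higher and 50 lower genes, and simulated groups without an effect, set against the same nonfailing arrays, shared a median of 1, with a 95% range of 0 to 377.8. The log2 differences correlated across genes, which are not independent replicates, with Pearson r = 0.962 and Spearman rho = 0.931. Without an effect the medians were 0.876 (0.634 to 0.952) and 0.845 (0.589 to 0.932), so rho lay within the range that shared controls alone give, and r just above it. The covariance was 0.0303 against 0.00511 simulated (0.00217 to 0.0136), a difference of 0.0251. With 8 nonfailing arrays for each comparison, the median r was 0.70, the median covariance 0.0251 and the median shared count 255.5 genes. Simulated groups without an effect, with controls split likewise, gave medians of -0.09, -0.000873 and 0. Without shared arrays the agreement thus stayed above these medians. At least 1.5-fold change in both was seen for 142 of the shared genes.

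**Figure D3:**
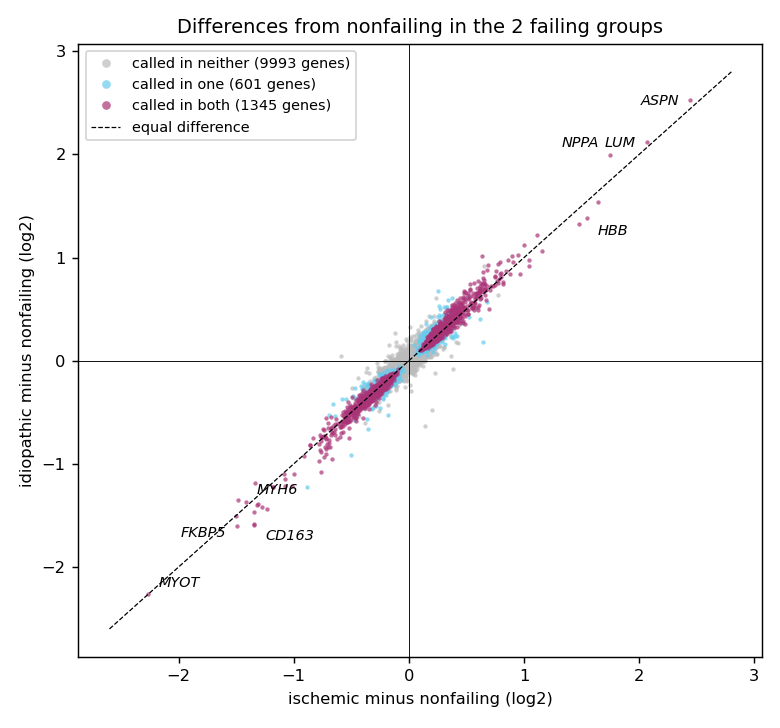
Log2 difference from nonfailing hearts of each of the 11939 genes in ischemic (horizontal) and idiopathic (vertical) hearts, coloured by whether a gene was called in neither, in 1 or in both comparisons. The points follow the dashed line of equal difference (r = 0.962), from MYOT at -2.27 and -2.26 to ASPN at 2.44 and 2.53, and both axes share the nonfailing arrays.

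The third comparison asked what separates ischemic from idiopathic failure. FOS, an immediate early transcription factor, was higher in ischemic hearts by 0.77 ± 0.15 log2 units (adjusted p = 0.00396) and exceeded the idiopathic mean in 69.4% of ischemic arrays. MYL7, the atrial regulatory light chain, was higher by 0.67 ± 0.14 (adjusted p = 0.0107), and GPNMB, a glycoprotein of macrophages and other cells, by 0.46 ± 0.08 (adjusted p = 0.000835, above the idiopathic mean in 79.6% of ischemic arrays). BEX1, a small adaptor protein, fell by 0.42 (SE 0.08, adjusted p = 0.00396), and PDE8B, a cyclic AMP phosphodiesterase, fell by 0.33 (SE 0.06, adjusted p = 0.00173), below the idiopathic mean in 88% of ischemic arrays. ZFP36, which destabilises cytokine messages, was higher by 0.35 ± 0.08 (adjusted p = 0.0278).

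These were 6 of 7 genes called, 5 higher and 2 lower, and the other was CPLANE2 (0.11 ± 0.02), a dim gene named after its value was seen. At an unadjusted p under 0.05 there were 806 genes. Means of BEX1 were 7.04 in nonfailing, 7.29 in ischemic and 7.71 in idiopathic hearts, and those of GPNMB 9.72, 10.1 and 9.65. FOS averaged 7.28 in nonfailing, 7.41 in ischemic and 6.65 in idiopathic hearts. MYL7 averaged 10.1, 10.3 and 9.65, while the other atrial genes MYL4 (0.32, adjusted p = 0.584), SLN (-0.02), NPPA (-0.25) and KCNA5 (0.01) were not called between the failing groups. Within the spike batch 0 genes were called between 3 ischemic and 7 idiopathic arrays, and FOS differed by 0.60, against 0.74 ± 0.16 (adjusted p = 0.0205) outside it.

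**Figure D4:**
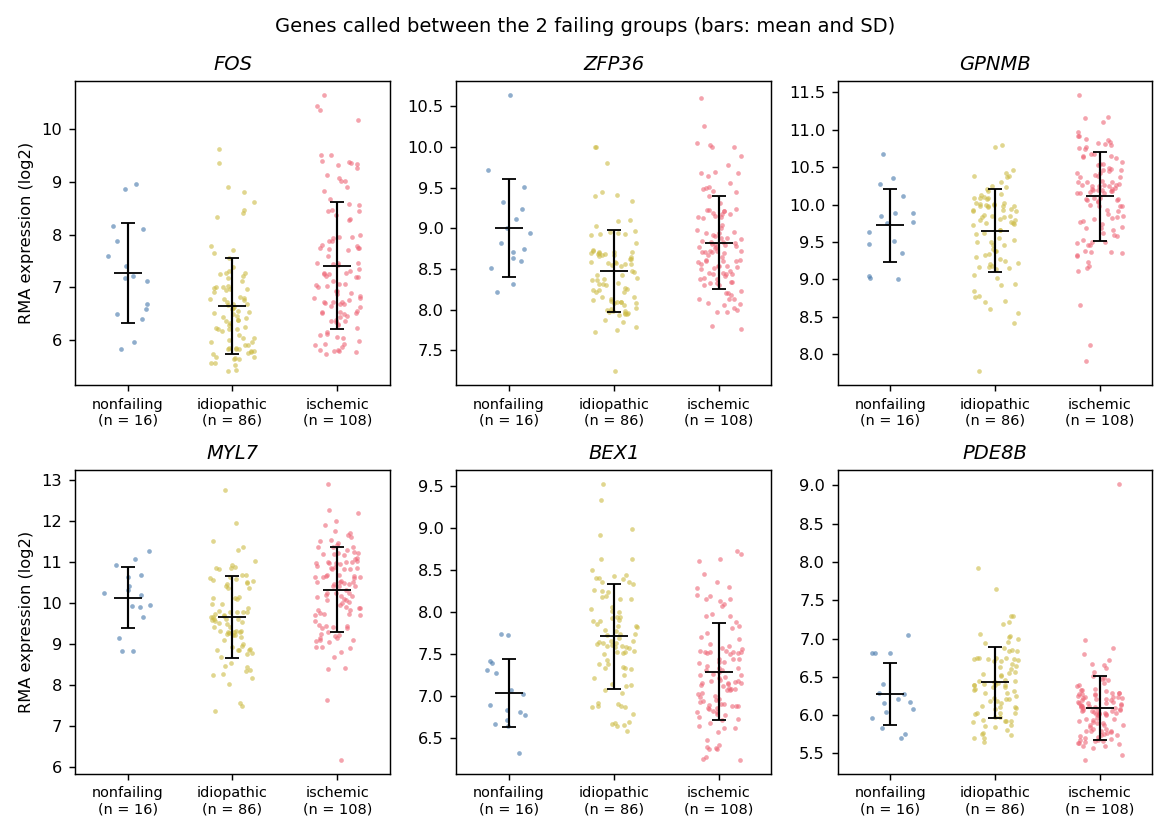
RMA expression (log2) of the 6 named genes called between ischemic and 86 idiopathic hearts, with 16 nonfailing hearts beside them, where each point is an array and black bars give the mean and SD. FOS, ZFP36, GPNMB and MYL7 lie higher and BEX1 and PDE8B lower in ischemic hearts, and the groups overlap widely for each gene.

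Immediate early genes rose in 2 of 23 (FOS and ZFP36) and fell in 0, or 10 and 0 adjusted over the list alone, with a median of 0.11 log2 units. Camera gave adjusted p = 4.58e-14, adjusted p = 0.0824 with an estimated correlation, and permutation adjusted p = 0.00644, the only list called by permutation. Atrial markers had 1 riser among 11, MYL7, or 2 adjusted over the list alone. The remaining 26 lists had 0 members called over all genes, with the most members adjusted over the list alone in beta-adrenergic signalling, where 3 fell. Camera at the preset correlation called 12 lists, 5 higher and 7 lower, and 0 with an estimated correlation. The panel genes differed by at most 0.25 in size, NPPA by -0.25, NPPB by -0.15, COL1A1 by 0.16 and PPARGC1A by -0.14, with none called.

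The call of MYL7 was lost without the degraded arrays (0.48, adjusted p = 0.445), that of ZFP36 without the spike batch (0.33, adjusted p = 0.104), and those of FOS (0.61, adjusted p = 0.0821) and ZFP36 (0.25, adjusted p = 0.343) with leukocyte and erythrocyte covariates. With the replicate number as a block, BEX1 (-0.36, adjusted p = 0.0829), MYL7 (0.65, adjusted p = 0.0746) and ZFP36 (0.31, adjusted p = 0.133) lost their calls, as did ZFP36 with the spike batch as a covariate (0.33, adjusted p = 0.0578).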

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

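The tests of RNA degradation for the genes lower or higher in failing hearts, and the test of the cardiomyocyte share, were chosen only after those results were seen. The glucocorticoid targets were written without genes already seen, but on the same arrays, so they are not independent support.

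Of the acute phase, cytokine and heat shock genes, 24 were called lower in at least 1 failing group, with a mean of -0.60 log2 units over these selected members against list medians of -0.26 and -0.38 in ischemic and -0.39 and -0.41 in idiopathic hearts, and the acute phase list lost its call in ischemic hearts (adjusted p = 0.0694 with an estimated correlation). With the 3' to 5' measures of RNA degradation as covariates 109% of that shift stayed (95% bootstrap interval 100 to 125), and with the neutrophil marker mean as a covariate 86.8% stayed (74.1 to 96.4), which argues against either as the whole cause. The neutrophil gene S100A8, at 9.45 in nonfailing and 8.57 and 8.23 in ischemic and idiopathic hearts, was called lower only in idiopathic hearts, and the neutrophil list had permutation adjusted p = 0.397 in ischemic and 0.00369 in idiopathic hearts. The nonfailing donor hearts may also have had a stronger glucocorticoid response, since 13 measured targets, written without FKBP5 and CD163, averaged -0.31 (-0.42 to -0.21) in failing hearts. Among them 5 fell, KLF9, SGK1, GLUL, CRISPLD2 and BCL6, and 0 rose. Others, such as TSC22D3 (0.0001 ischemic, -0.07 idiopathic) and DDIT4 (0.06, -0.10), were not called. Camera with an estimated correlation gave unadjusted p = 0.00575 and 0.00422. Whether such a response would raise or lower the acute phase, cytokine and heat shock genes was not tested. How much of their shift it could carry was not tested either. Heart failure itself, and the donors' care before the hearts were taken, also stay open and untested.

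Immediate early genes averaged 0.19 log2 units more in ischemic than in idiopathic hearts over 23 genes, of which only FOS and ZFP36 were called, both calls ended with leukocyte and erythrocyte covariates although differences of 0.61 and 0.25 stayed of 0.77 and 0.35, and the list had adjusted p = 0.0824 with an estimated correlation. With the RNA degradation covariates 112% of the shift stayed (94.2 to 149), and without the 10 arrays of the spike batch 97% stayed (lower bound 85.6), which argues against both as the whole cause. With the neutrophil marker mean as a covariate 69.2% stayed, and the interval of 41.4 to 88.7 includes a loss of more than 50%, so a share of neutrophils in ischemic tissue and a response of the heart's own cells cannot be told apart. The neutrophil genes S100A8 and S100A9 averaged 8.57 and 7.33 in ischemic against 8.23 and 7.01 in idiopathic hearts, though neither was called between them. The cause of heart failure, which the groups name, stays open, and the delay before freezing, to which immediate early genes respond, was not tested.

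Of the extracellular matrix and fibroblast genes, 30 were called higher in at least 1 failing group, with a mean of 0.80 log2 units over these selected members. With an estimated correlation neither list was called, at adjusted p = 0.103 and 0.126 for matrix and 0.0694 and 0.0724 for fibroblast genes in ischemic and idiopathic hearts. With the RNA degradation covariates 98% of the shift stayed (lower bound 89.5). A loss of cardiomyocytes alone would raise the markers of other cell types alike. Fibroblast markers shifted by 0.62 and endothelial markers by -0.01 on average, a difference of 0.63 (0.47 to 0.80). List medians were 0.36 and 0.43 against 0.04 and 0.06 in ischemic and idiopathic hearts. The test cannot exclude a lower share of cardiomyocytes in which fibroblasts alone took their place. More fibroblasts, with or without fewer cardiomyocytes, or more matrix expression per fibroblast could each give this difference. They were not tested against each other, and this hypothesis was found and tested on the same arrays.

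Single genes that differed between the failing groups, by the limma test of that difference, were FOS (0.77), MYL7 (0.67), GPNMB (0.46), ZFP36 (0.35), CPLANE2 (0.11), BEX1 (-0.42) and PDE8B (-0.33). Gene lists that differed between them by camera at the preset correlation had median log2 differences, ischemic minus idiopathic, of 0.128 for neutrophil, 0.107 for immediate early, 0.0971 for macrophage, 0.0649 for acute phase and 0.051 for erythrocyte genes. The lower lists were sarcomere at -0.111, oxidative phosphorylation at -0.0588, endothelial markers at -0.0436, cardiac transcription factors at -0.0417, fatty acid oxidation at -0.0355, adipocyte markers at -0.0261 and beta-adrenergic signalling at -0.0195. None of these 12 lists was called with an estimated correlation. The poly-A spike control probe sets, which lie outside the genes compared, showed a signal in 10 arrays, at a mean of at least 10.6 against at most 3.90 in the others.

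Random splits of the arrays into groups of the same sizes were drawn 100 times, the real one included. The real split called 1581 genes for ischemic against nonfailing hearts, reached by 1 of 100 splits with 334 as the highest other, and 1710 for idiopathic against nonfailing, reached by 1 of 100 with 12 as the highest other. At the 5% level, random grouping of interchangeable arrays can be excluded for both counts. Groups of unequal spread are not interchangeable, and the test with unequal variances per gene called 985 and 1186 genes. For ischemic against idiopathic hearts 7 genes were reached by 2 of 100 splits. That is under 5%, but 100 splits are too few to exclude chance at that level. The other split called 1581 genes, which points to a structure of the arrays that the groups do not follow and whose nature was not tested. That this number equals the count for ischemic against nonfailing hearts is a coincidence, since 139 genes were in both sets. The numbers of lists called by camera at the preset correlation, 12 in each comparison, were reached by 16 of 100 splits for ischemic against nonfailing (highest other 17), 2 of 100 for idiopathic against nonfailing (13) and 10 of 100 for ischemic against idiopathic hearts (16). Only the second of these list counts was reached by under 5% of the splits, and 100 splits are too few to exclude chance firmly for it.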

How the results depend on the processing

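The alternatives without the spike batch or degraded arrays, with the spike batch as a covariate, with centring on normalization probe sets and with leukocyte and erythrocyte covariates, and the permutation of lists, were chosen after seeing the data. For ischemic against nonfailing hearts the count of 1581 genes became 2411 with 2 residual components removed, 606.5 as the median of draws of 16 arrays per group and 985 with unequal variances per gene. For idiopathic against nonfailing hearts 1710 became 662.5 with 16 arrays per group, and in both the smaller groups lower the power by construction. For ischemic against idiopathic hearts the count of 7 became 26 with array weights, 20 with RNA quality covariates, 84 with 2 residual components, 11 with centring on the normalization probe sets, 4 with leukocyte and erythrocyte covariates and 0 with 16 arrays per group. The 2 components came from residuals of the same fit, so they left each difference unchanged. They took spread out of the tests by construction, so the rises to 2411 and 84 are not evidence of more differences. Where no other cause is given, the cause was not tested. The other alternatives kept each gene count within 1.5 times its value. Lists called fell from 12 to 1, 2 and 0 with an estimated correlation, which widens the test's null by construction, and to 5 for ischemic against nonfailing hearts with the filter on dim genes. The overlap of 1345 genes became 142 with at least 1.5-fold change in both and 255.5 with split controls, both with stricter demands or fewer arrays.

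With leukocyte and erythrocyte covariates, which hold these genes, ALAS2 (-0.00261) and HBD (-0.0454) reversed for ischemic against nonfailing hearts. With the probe set of largest interquartile range, GNAS (-0.0163 ischemic, -0.0866 idiopathic) and NFATC1 (-0.0301 ischemic) reversed, since another probe set stood for the gene. Of the named genes called, 29 of 86 for ischemic against nonfailing, 38 of 93 for idiopathic against nonfailing and 2 of 6 between the failing groups, GPNMB and PDE8B, kept their call in each alternative that tested them. Centring on the normalization probe sets moved the median of all genes from 0.02 to 0.08 log2 units for ischemic hearts, below 0.1, and 1317 of the 1581 genes were also called there. Replicate numbers as a block, although they do not pair the samples (1 of 86 ischemic and idiopathic pairs correlated best with its own number), called 1436, 1783 and 5 genes, of which 894, 1108 and 3 were among those called before, and NRAP lost its call (-0.47, adjusted p = 0.531). Quantile normalization again and median centring moved nothing, as the table was already aligned, and show nothing about stability. Dim genes lie near the arrays' background, where RMA compresses differences, so small changes among them are not resolved.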

Other observations

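The genes and lists described here were chosen after their first members had been noticed, and the members tested for each list were written down before their values were seen. Both steps used the same arrays, so the results are not independent support for a list.

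Some members of further gene groups differed from nonfailing hearts in both forms of failure. Interferon-stimulated genes, which respond to viral and other danger signals, were first noticed through IFIT1 (0.71 ischemic, 0.72 idiopathic) and IFI44L (0.79, 0.95). Over 19 other measured members the mean difference of the failing hearts was 0.19 log2 units (95% bootstrap interval 0.06 to 0.31), and 4 rose in ischemic and 6 in idiopathic hearts, among them MX1 (0.49, 0.57) and IFIT3 (0.26, 0.30), with 0 that fell. MHC class II genes, which present antigen, were noticed through HLA-DPA1 (0.88, 0.84), and 10 others averaged 0.32 (0.12 to 0.50). Of these, 3 rose and 0 fell in each form of failure, HLA-DPB1 (0.62, 0.67), CD74 (0.57, 0.56) and HLA-DMB (0.44, 0.38). HLA-DOA (-0.04, -0.06) had the opposite sign and was not called. With an estimated correlation the unadjusted p was 0.216 and 0.141 for the interferon and 0.127 and 0.155 for the class II genes, so neither list was called by that test.

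Amino acid stress response genes, targets or partners of the transcription factor ATF4, were noticed through ASNS (-0.74, -0.68) and MTHFD2 (-0.72, -0.90). Over 19 other measured members the mean was -0.18 log2 units (-0.28 to -0.09), and 8 fell in ischemic and 11 in idiopathic hearts, with 0 that rose. ATF4 itself (-0.57, -0.63), CEBPG (-0.55, -0.59), the transfer RNA exporter XPOT (-0.36, -0.36) and the synthetase AARS1 (-0.24, -0.24) fell, with unadjusted p = 0.00103 and 0.000442 with an estimated correlation. DDIT3 (0.13, 0.10) and VLDLR (0.12, 0.24) had the opposite sign and ATF5 (0.01, -0.02) hardly differed, none of them called. A lower amino acid stress response in failing than in donor hearts is a hypothesis from these values, and whether it reflects heart failure or the state of the donor hearts was not tested.

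Single genes outside the lists also fell in both groups, among them the lipid droplet protein PLIN2 (-1.01 ischemic, -1.21 idiopathic), the cell cycle inhibitor CDKN1A (-0.70, -0.83) and the thioredoxin reductase TXNRD1 (-0.77, -0.89). The LIM domain protein LMCD1 (-1.07, -1.21) and the metallothionein MT1M (-1.07, -1.15) fell as well. The chemokine CXCL12 (0.64, 0.86), the heparin-binding growth factor PTN (0.74, 0.81), the thyroid hormone binding protein CRYM (0.69, 0.93) and the complement component C6 (0.63, 1.02) rose.

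The spread of genes within the failing groups was compared through absolute deviations from the group median. At an adjusted p under 0.05 limma found 0 genes with a larger and 0 with a smaller spread in ischemic hearts. A count of 0 is reached by 100 of 100 random splits by construction, the highest other giving 1, so the splits decide nothing here. At an unadjusted p under 0.05 there were 1718 with a larger and 19 with a smaller spread, a count reached by 1 of 100 splits with 983 as the highest other. Whether ischemic hearts vary more from heart to heart stays open.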
